A study of Mus musculus with 6 samples.

How the data were processed

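Total RNA from the esophageal epithelium of 6 mice (3 with ED-L2-Cre and floxed *Klf4*, 3 floxed littermates without Cre) was extracted with a column kit, and 100 ng per animal was amplified from poly(T)-primed cDNA and labelled with biotin, per the labels' protocols. The deposited table holds log2 values for 28853 probe sets on 6 arrays. Partek 6.4 is the only tool named, per the submitters' processing notes. The background correction, normalization and summarization behind the values are not given in the sources used here, and they set how far differences of dim genes are compressed. The log2 scale was taken from the values, whose medians per array lay between 5.01 and 5.13 and whose maxima lay between 13.99 and 14.67. Read depth does not apply to arrays, and the number of arrays limits the precision.

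Probe sets were named from the platform annotation, with symbols updated through Entrez identifiers to those of assembly GRCm38.p6, which served only for names and for the order of neighbouring genes. Of the 28853 probe sets, 21789 named 1 gene, 1621 several and 5443 were unnamed here. Among those naming 1 gene, 21698 identifiers matched and 91 kept the annotation's symbol. For the 999 genes with more than 1 probe set, the probe set with the highest mean over the 6 arrays was used, which gave 19938 genes. Genes with probe sets passing in opposite directions numbered 0. No values were filtered or renormalized in the main comparison. No genomic positions are printed, since the files name no genome build.

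Differences between arrays labelled mutant and arrays labelled control were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, genotype only, 4 residual degrees of freedom and 7.58 after moderation), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Errors of differences are the moderated SE. A permutation test of 3 arrays against 3 cannot go below an exact p of 0.1 and was not used for single genes. Gene lists, 41 in number, covered squamous differentiation, proliferation, signalling, metabolism and markers of other cell types, and were tested with camera (preset inter-gene correlation 0.01), with an estimated correlation and with fry. Of 1027 list entries, 952 were matched to a probe set naming 1 gene. Of the lists, 7 had a median, mean or test of differing sign, none of them called: macrophage, NF-kB, gastric, adipocyte, suprabasal differentiation, housekeeping, and nerve. The difference of the genotype effect between sexes was tested as an interaction term. Python 3.11.15 and matplotlib 3.10.9 served for annotation and plots.

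The samples, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule takes *Klf4*. It takes the 12 genes that rose most and the 12 that fell most among those passing with separate groups. From each list it takes up to 4 passing members, or up to 2 with the smallest p where none passes. It also takes 12 fixed genes of squamous epithelium and the cell cycle, and sex-linked genes. The probe set of *Cdkn1a*, one of the fixed genes, names several genes and is not reported. A planned check of RNA quality from the 3' and 5' control probe sets was not analysed here, because the gene table used does not name those probe sets.

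The steps were tested on simulated data with the real means and limma's moderated spreads for the comparison of mutant against control (19938 genes, 50 changed at each size). Moderated spreads vary less between genes than the unmoderated ones, so the recovery may be better than in the real data. Changes of 0.5, 1, 2 and 3 on the log2 scale were recovered in 20%, 94%, 98% and 100% of cases, with 4 false among 160 calls. With no gene changed, 2 genes and 0 lists were called. The genes were simulated independently of each other, while the estimated correlation within called lists reached 0.74. The 0 lists therefore say nothing about false calls of lists whose genes vary together. Alternatives covered quantile normalization, median centring, a filter at the 40th percentile of mean signal (4.35 on the log2 scale), other rules for probe sets, the replicate number as a block, sex as a covariate, an intensity trend, no moderation, array weights, a 1.5-fold minimum and each array left out. The median difference of all genes was 0.022 as deposited, 0.013 after quantile normalization and 0.044 after median centring. A fibroblast and muscle score as a covariate and the females alone were added after seeing the data.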

Results

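Gene expression was measured with microarrays in the esophageal epithelium of 6 mice aged 3 months. In 3 animals the transcription factor gene *Klf4* was flanked by loxP sites on both copies and the ED-L2-Cre transgene, whose promoter is active in squamous epithelium such as that of the esophagus, was present. The 3 controls were littermates of matching sex with the same floxed gene and no Cre. Each genotype held 1 male (replicate 1) and 2 females (replicates 2 and 3), all on a mixed genetic background, and each array was one animal. The deposited table held log2 values for 28853 probe sets, of which 21789 named a single gene, and 19938 genes were compared. Correlations between arrays, taken across these 19938 genes, lay between 0.974 and 0.992. With 3 arrays per genotype, the number of animals limits the precision of every difference.

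The first question was whether the targeted gene itself differed between the groups. *Klf4* (probe set 10513008) read 9.75, 10.15 and 10.06 on the 3 arrays labelled control and 10.28, 10.50 and 10.28 on the 3 labelled mutant. The means were 9.99 ± 0.21 and 10.35 ± 0.13 (SD, n = 3 each), so the signal was not lower on the arrays labelled mutant. The difference was 0.37 ± 0.13 (SE) on the log2 scale and did not pass the test (limma adjusted p = 0.314). The sources used here give neither the part of the gene that Cre removes nor the position of the probes, and a probe outside the removed part checks nothing. Every direction given here therefore rests on the labels: "rose" and "fell" describe arrays labelled mutant relative to arrays labelled control. The sexes in the labels were matched by the arrays. *Xist*, transcribed from the inactive X chromosome, read 3.49 and 3.76 on the 2 male arrays and 8.77 to 9.24 on the 4 female arrays. The Y-linked gene *Eif2s3y* read 7.06 and 7.37 on the male arrays and 2.51 to 2.75 on the female arrays.

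The main comparison asked which genes changed in esophageal epithelium when *Klf4* was targeted. Genes of the *Sprr2* family, which encode small proline-rich proteins of the cornified envelope, rose most. *Sprr2f* went from 5.29 ± 0.95 on the arrays labelled control to 11.60 ± 0.34 on those labelled mutant (SD, n = 3 each), a 79.8-fold difference (adjusted p = 0.00161). *Sprr2g* went from 4.30 ± 0.27 to 10.09 ± 0.22, a 55.3-fold difference with the smallest adjusted p of the genes named here, 2.82e-05. Its control mean lies under the dim limit of 4.35 on the log2 scale, so the size of that fold is uncertain. The beta-defensin gene *Defb3*, which encodes an antimicrobial peptide, rose 26.5-fold (4.73 ± 0.51 on the log2 scale, SE; adjusted p = 0.0118). The 3 genes that fell most encode secreted peptides or proteins. The neuropeptide gene *Nmu* fell by 3.23 ± 0.42, *Slurp1* by 3.19 ± 0.16 and *Slurp2* by 3.12 ± 0.21 on the log2 scale (SE; adjusted p = 0.0176, 0.000554 and 0.00161). *Slurp1* and *Slurp2* encode small secreted proteins of the Ly6 family. In all, 207 of the 19938 genes passed an adjusted p of 0.05 in limma, 73 higher and 134 lower on the arrays labelled mutant, and 203 of them differed at least 1.5-fold. All 207 had non-overlapping groups, as did 18.1% of all genes, where chance gives 10%. The count depended on single arrays: it was 106 without control 2, 44 without control 3, 93 without mutant 1, 93 without mutant 2 and 102 without mutant 3. It was 83 in the 4 females alone, 370 with array weights and 7 without moderation of the variances.

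**Figure D1:**
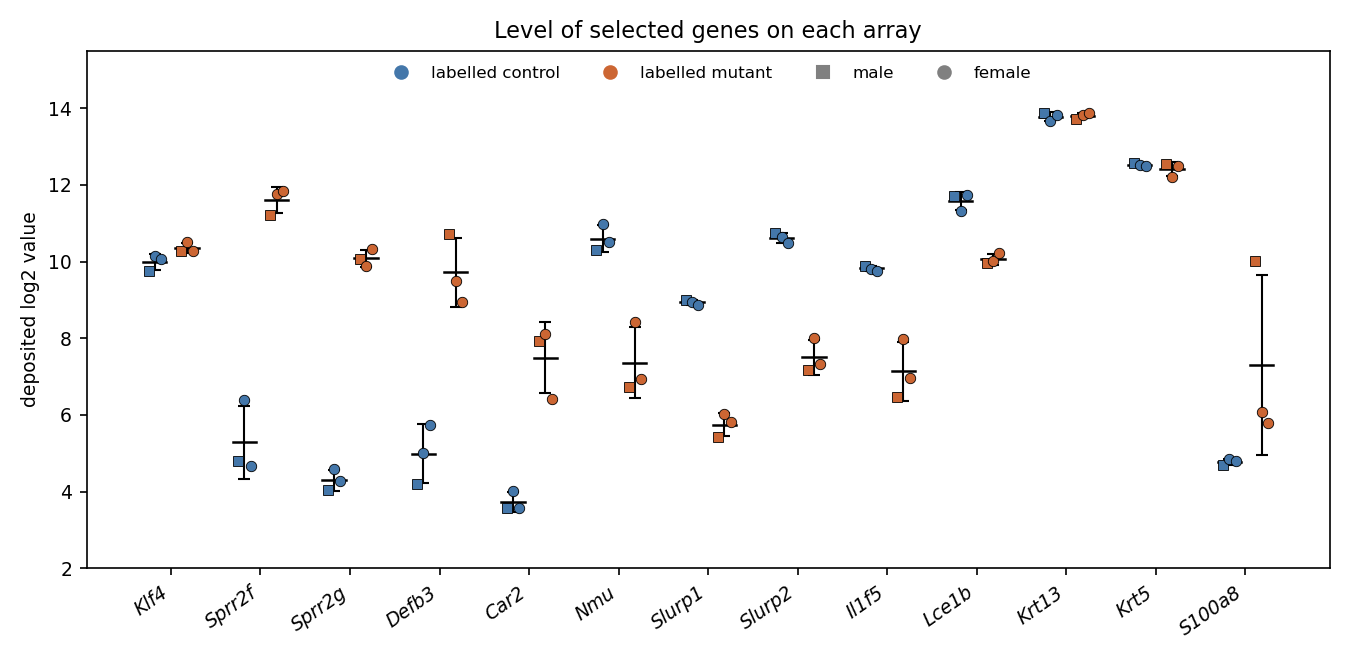
Deposited log2 values (vertical axis) of 13 genes on each array; squares are males, circles females, blue arrays labelled control and orange arrays labelled mutant, with black bars for the mean and SD of 3 arrays. *Sprr2f* lies near 11.60 on the arrays labelled mutant and 5.29 on those labelled control, and *Klf4* is not lower on the arrays labelled mutant. *S100a8* is highest on mutant 1, at 10.01, with mutants 2 and 3 at 6.08 and 5.80, above the controls.

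Apart from the *Sprr2* genes and *Defb3*, the 12 largest increases were spread over several functions. *Car2*, encoding a carbonic anhydrase, rose by 3.76 ± 0.41, the flavin monooxygenase gene *Fmo9* by 3.54 ± 0.42 and the nonclassical class I gene *H2-M10.5* by 3.90 ± 0.57 (log2, SE). The control mean of *Car2*, 3.73, lies under the dim limit, so the size of its rise is uncertain. *Ltbp1*, whose product holds latent TGF-beta in the matrix, rose by 2.79 ± 0.47, and *Papss2*, encoding an enzyme that makes the sulfate donor of the cell, by 2.71 ± 0.44. Their adjusted p-values in limma lay between 0.0118 and 0.0451. Among the 12 largest decreases, *Il1f5*, encoding the receptor antagonist of the IL-36 cytokines, fell by 2.68 ± 0.34. The kallikrein protease gene *Klk5* fell by 2.50 ± 0.39, and the sodium-hydrogen exchanger gene *Slc9a3* fell by 2.56 ± 0.40. *Nt5e*, whose product forms extracellular adenosine, fell by 2.16 ± 0.24. The differences of *Mab21l4*, *Clmn*, *Dkkl1*, *AU021092* and *Fndc9* were -2.66, -2.39, -2.29, -2.22 and -2.18. Of the 24 genes with the largest changes, 11 still passed without control 3 and between 16 and 20 without any other single array. Those lost without control 3 were *H2-M10.5*, *Car2*, *Fmo9*, *Ltbp1*, *Papss2*, *Nmu*, *Il1f5*, *Mab21l4*, *Slc9a3*, *Klk5*, *AU021092*, *Fndc9* and *Nt5e*. Of the 17 alternatives tried, *Ltbp1* and *Klk5* did not pass in 9, and *Papss2* and *Slc9a3* in 7.

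Genes of terminal differentiation moved in opposite directions by family. Of 48 measured genes on the suprabasal differentiation list, 7 rose, all of the *Sprr2* family, and 1 fell, with 40 not passing; adjusted over the list alone, 8 rose and 9 fell. *Sprr2i* and *Sprr2h* rose by 4.76 ± 0.25 and 4.56 ± 0.25 (log2, SE). The gene that fell was the envoplakin gene *Evpl* (-1.03 ± 0.16), named after its values were seen. The list as a whole was not called (camera adjusted p = 0.850), and its median, -0.044, differed in sign from its mean, 0.53, and from the upward direction of the test. On the late cornified envelope and granular layer list, 9 of 28 genes fell, none rose and 19 did not pass; adjusted over the list alone, 13 fell and 2 rose. Its examples were the hornerin gene *Hrnr* (-2.07 ± 0.34), *Lce1l* (-1.89 ± 0.32), *Lce1b* (-1.52 ± 0.14) and *Lce1a1* (-1.15 ± 0.17), of which *Hrnr* and *Lce1l* did not pass in 10 of 17 alternatives and *Lce1a1* in 7. The list's median was -0.63 (camera adjusted p = 3.11e-11; adjusted p = 0.429 with an estimated correlation). Members of the *Sprr2* and of the *Lce1* families are near-identical in sequence, so signal can be shared between them and the values of single members are uncertain.

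These families lie in the epidermal differentiation complex on chromosome 3, where their order was taken from the annotation of assembly GRCm38.p6. Across the genome, all 9 measured *Sprr2* genes were higher on the arrays labelled mutant, 8 of them past the threshold, with a median of 4.43. Both counts include *Sprr2j-ps* (1.21), a pseudogene by its symbol. All 13 *Lce1* genes were lower, 10 past the threshold, with a median of -0.89. The 4 genes *Sprr1a*, *Sprr1b*, *Sprr3* and *Sprr4* did not pass, with differences between -0.19 and 0.57. None of the 5 *Lce3* genes passed, with differences between -0.37 and -0.015. With each array centred on its median, 7 *Sprr2* and 6 *Lce1* genes passed and all kept their direction, while 1 *Lce3* gene turned to higher.

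**Figure D2:**
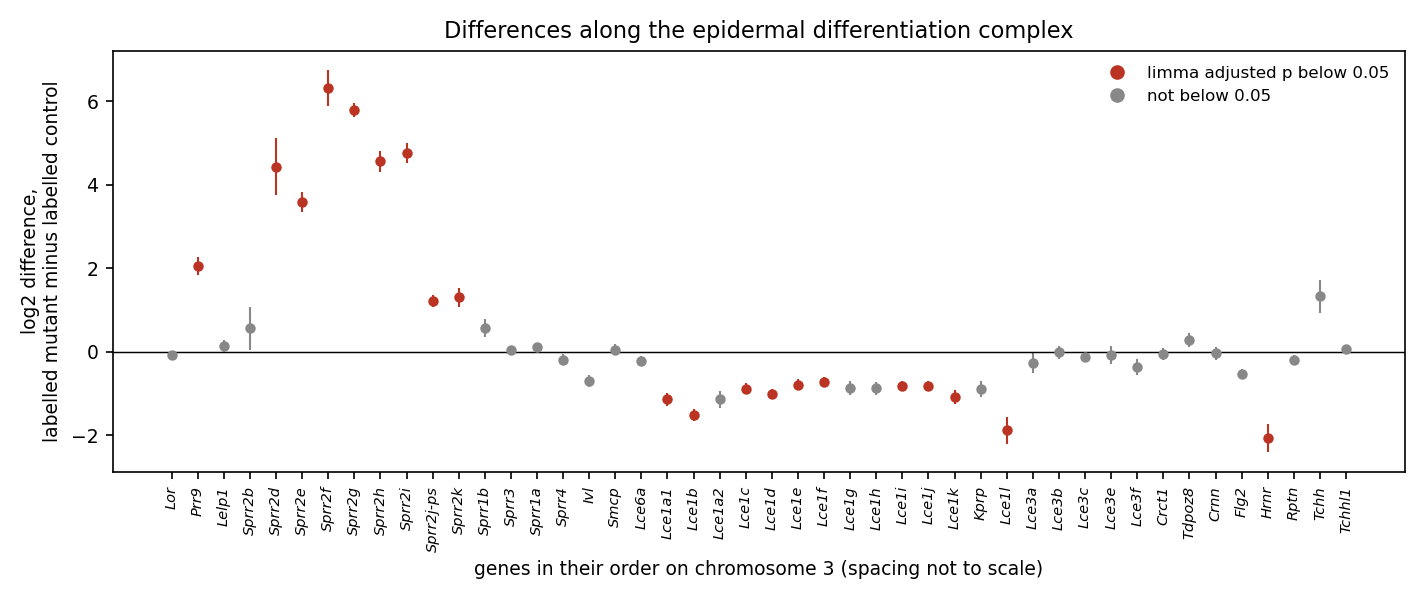
Log2 difference, arrays labelled mutant minus arrays labelled control (vertical axis), of 46 genes in their order along the epidermal differentiation complex (horizontal axis, not to scale); points are estimates, bars are the SE from limma, and red marks an adjusted p under 0.05. *Sprr2* genes lie up to 6.32 above zero and *Lce1* genes reach -1.89, and the direction rests on the labels.

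Abundant keratins and regulators of squamous epithelium gave differences that did not pass. The suprabasal keratins *Krt4* and *Krt13* differed by -0.043 ± 0.098 and 0.027 ± 0.102, and the basal keratins *Krt5* and *Krt14* by -0.11 ± 0.11 and 0.16 ± 0.19 (log2, SE). *Lor*, encoding loricrin, differed by -0.079 ± 0.099, and the basal cell regulator *Trp63* by -0.080 ± 0.121. *Klf5*, a related factor of proliferating epithelium, differed by 0.28 ± 0.089 (adjusted p = 0.249) and *Sox2* by 0.51 ± 0.16 (adjusted p = 0.231). *Ivl*, encoding involucrin, differed by -0.70 ± 0.14 (adjusted p = 0.0779) from a control mean under the dim limit of 4.35. The proliferation marker *Mki67* and the cyclin gene *Ccnd1* differed by 0.17 ± 0.29 and -0.016 ± 0.243. Control means of *Krt4*, *Krt13* and *Lor* were 13.68, 13.78 and 13.33, near the array maxima of 13.99 to 14.67. Differences of such bright genes may be compressed, so their small size does not show that these genes were unchanged. Of the 17 genes on the list named stress and hyperproliferation keratins, 12 were higher and 5 lower on the arrays labelled mutant. Past the threshold, *Krt80* (-1.49 ± 0.24) and *Krt76* (-1.16 ± 0.12) fell and 15 did not pass. *Krt80* lost its call in 9 of 17 alternatives, and these 2 genes do not stand for the list. With the list's own adjustment, 5 rose and 2 fell, and the list was not called (camera adjusted p = 0.238).

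Of the 41 gene lists, camera with a preset inter-gene correlation called 13, of which 3 were higher and 10 lower on the arrays labelled mutant. None was called with an estimated correlation, where 4 lists had an unadjusted p under 0.05, and none by fry, where 10 had. In the other splits of the 6 arrays into 3 and 3, which mix the labelled groups, camera with the preset correlation called between 4 and 13 lists. That count was made after seeing the data. The number of called lists therefore does not set the labels apart from other groupings. The DNA replication and G1/S list was higher (31 genes, none past the threshold, median 0.16, camera adjusted p = 0.0397; adjusted p = 0.906 with an estimated correlation), led by *Ccne1* at 1.11 ± 0.21 (adjusted p = 0.0701). That call was lost without control 2, without mutant 1 and without mutant 3, with medians of -0.055, 0.13 and -0.055, and with median centring (adjusted p = 0.0521). The median was 0.29 without control 1, 0.25 without control 3 and 0.34 without mutant 2. The mitosis list was not called (31 genes, median 0.13, camera adjusted p = 0.185), and the 2 lists were not tested against each other. The unfolded protein response list was higher (24 genes, median 0.48, camera adjusted p = 0.00232; adjusted p = 0.819 with an estimated correlation), and 1 member, the asparagine synthetase gene *Asns*, rose (0.52 ± 0.089) but did not pass in 12 of 17 alternatives. Its mean per array, relative to the mean of all 6, was 0.70 on mutant 1 and -0.078 and -0.087 on mutants 2 and 3. Its median was 0.28 in the females alone. Without mutant 1 its median was 0.12 and the call was lost (adjusted p = 0.367), as it was without control 2 (adjusted p = 0.0625). The list of serpins, proteases and inhibitors was also higher (36 genes, median 0.21, camera adjusted p = 0.00892; adjusted p = 0.589 with an estimated correlation). In it, *Ctsc*, encoding cathepsin C, rose by 1.14 ± 0.14 and *Klk5* fell, 8 rose and 2 fell when adjusted over the list alone, and the list's call was lost without control 2 (median 0.12, adjusted p = 0.0944) and without mutant 1 (adjusted p = 0.0503).

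Lists of signalling and matrix genes were lower by small amounts. The basal keratinocyte list had a median of -0.21 (27 genes, none past the threshold, 5 fell when adjusted over the list alone, camera adjusted p = 0.000449; adjusted p = 0.429 with an estimated correlation), with the laminin genes *Lama3* and *Lamb3* at -0.50 ± 0.10 and -0.49 ± 0.10. The integrin, matrix and migration list had a median of -0.21 over 36 genes, and the fibronectin gene *Fn1* fell by 1.26 ± 0.18, and 6 fell and 1 rose when adjusted over the list alone (camera adjusted p = 0.000449; adjusted p = 0.429 with an estimated correlation). Its median was -0.082 without control 2, -0.085 with the fibroblast and muscle score described below as a covariate and -0.39 without dim probe sets, and it kept its call each time. The TGF-beta and BMP list had a median of -0.16 over 28 genes and the hypoxia and glycolysis list -0.27 over 25, with no member past the threshold in either. Their camera adjusted p-values were 0.000662 and 0.0013, and each had an adjusted p = 0.429 with an estimated correlation. With the score as a covariate their medians were -0.13 and -0.15. Fibroblast genes were lower on the same arrays, and the share of stroma in these lists was not separated from a change in the epithelium. In the list of Wnt and beta-catenin targets (36 genes, median -0.090), the ligand genes *Wnt5a* and *Wnt4* fell by 1.58 ± 0.15 and 0.69 ± 0.10. *Wnt4* did not pass in 11 of 17 alternatives, and a second probe set of it read -0.41 and did not pass. The list's camera adjusted p was 0.0104 (adjusted p = 0.589 with an estimated correlation), and 0.106 without control 1. The median was -0.058 without control 1 and without mutant 1, and -0.14 without dim probe sets. In the females alone it was -0.011 and the call was lost (adjusted p = 0.178). The interferon list (25 genes, median -0.077, none past the threshold) had a camera adjusted p of 0.0101 (adjusted p = 0.589 with an estimated correlation) and lost its call without control 1 and without mutant 2 (adjusted p = 0.122 and 0.0856) and without dim probe sets (adjusted p = 0.204). Its median was -0.12 without control 3, and in the females alone it was -0.14 and the call was lost (adjusted p = 0.148).

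Several lists that were not called held single genes that changed, many of them only with all 6 arrays: of the 52 named genes that passed, 15 still passed without control 3 and between 27 and 33 without any other single array. On the NF-kB, cytokines and chemokines list, *Il1f6*, encoding IL-36 alpha, and *Il18* fell by 2.04 ± 0.30 and 1.63 ± 0.25, and the IL-1 receptor antagonist gene *Il1rn* rose by 0.84 ± 0.10, while 37 of 40 genes did not pass. The 40 leave out *Il1f5*, which belongs on this list under its newer name but was not matched to it, and which fell. *Dsc2*, encoding a desmosomal cadherin, rose by 0.85 ± 0.12 as the only 1 of 14 desmosome genes. The connexin gene *Gjb5* fell by 0.75 ± 0.12 as the only 1 of 27 junction genes, where 3 rose and 4 fell when adjusted over the list alone. In the barrier lipid list, *Sptlc1*, encoding a subunit of the first enzyme of sphingolipid synthesis, rose by 1.46 ± 0.12 and the ceramidase gene *Acer3* fell by 0.93 ± 0.16, with 39 of 41 not passing; adjusted over the list alone, 5 rose and 3 fell. The retinol dehydrogenase gene *Rdh10* rose by 1.17 ± 0.13, 1 of 23 retinoid genes. The cystine transporter gene *Slc7a11* rose by 0.88 ± 0.11 and *Gstm2* fell by 0.94 ± 0.15 among 30 antioxidant and xenobiotic genes, where 1 rose and 4 fell when adjusted over the list alone. *Spry1*, an inhibitor of growth factor signalling, fell by 0.81 ± 0.12, 1 of 25 genes on the EGFR and MAPK list, but adjusted over that list alone 7 rose and 3 fell. Of the 17 alternatives tried, *Acer3* and *Gjb5* did not pass in 11, *Gstm2* and *Spry1* in 10, *Il18* in 9, *Dsc2* in 8 and *Il1rn* and *Slc7a11* in 6, all with the same direction.

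Fibroblast and muscle markers were lower on the arrays labelled mutant, while other markers of cells beneath the epithelium moved in both directions. All 21 fibroblast and lamina propria genes were lower, with a median of -0.78, and *Col1a2*, *Sparc* and *Thy1* fell by 1.30 ± 0.19, 1.10 ± 0.17 and 0.58 ± 0.10, of which *Thy1* did not pass in 14 of 17 alternatives. Adjusted over the list alone, 20 fell. The list's camera adjusted p was 9.7e-21, and its adjusted p = 0.429 with an estimated correlation. Smooth muscle genes had a median of -0.74 with none of 12 past the threshold; adjusted over the list alone, 8 fell and 1 rose (camera adjusted p = 1.7e-06; adjusted p = 0.487 with an estimated correlation). Skeletal muscle genes had a median of -0.80 with none of 30 past the threshold (camera adjusted p = 0.00335; adjusted p = 0.849 with an estimated correlation). The mean of the skeletal muscle genes ranged from -1.77 on control 1 to 1.96 on control 2 and from -1.71 on mutant 3 to 0.45 on mutant 1, so the groups overlapped. The skeletal muscle call was lost without control 2 (median -0.010), without control 3 (median -0.53) and without mutant 3 (median -0.16), and the median was -2.10 without control 1, -1.30 without mutant 1 and -2.62 in the females alone. Of 16 endothelial genes above the dim limit 8 were lower, with a median of -0.015, and *Flt1*, a VEGF receptor gene, fell by 1.90 ± 0.19 (adjusted p = 0.00982). In the macrophage and dendritic list *Lyz2* fell by 1.57 ± 0.27 and *Cd68* rose by 1.11 ± 0.17, and they did not pass in 9 and 8 of 17 alternatives. With a score of the fibroblast and muscle genes as a covariate, an alternative chosen after seeing the data, 270 genes passed, including 169 of the 207 and all 24 with the largest changes. That covariate left the fibroblast list at a median of -0.64, so it did not remove the difference in stroma, and it turned the skeletal muscle list to 0.76.

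**Figure D3:**
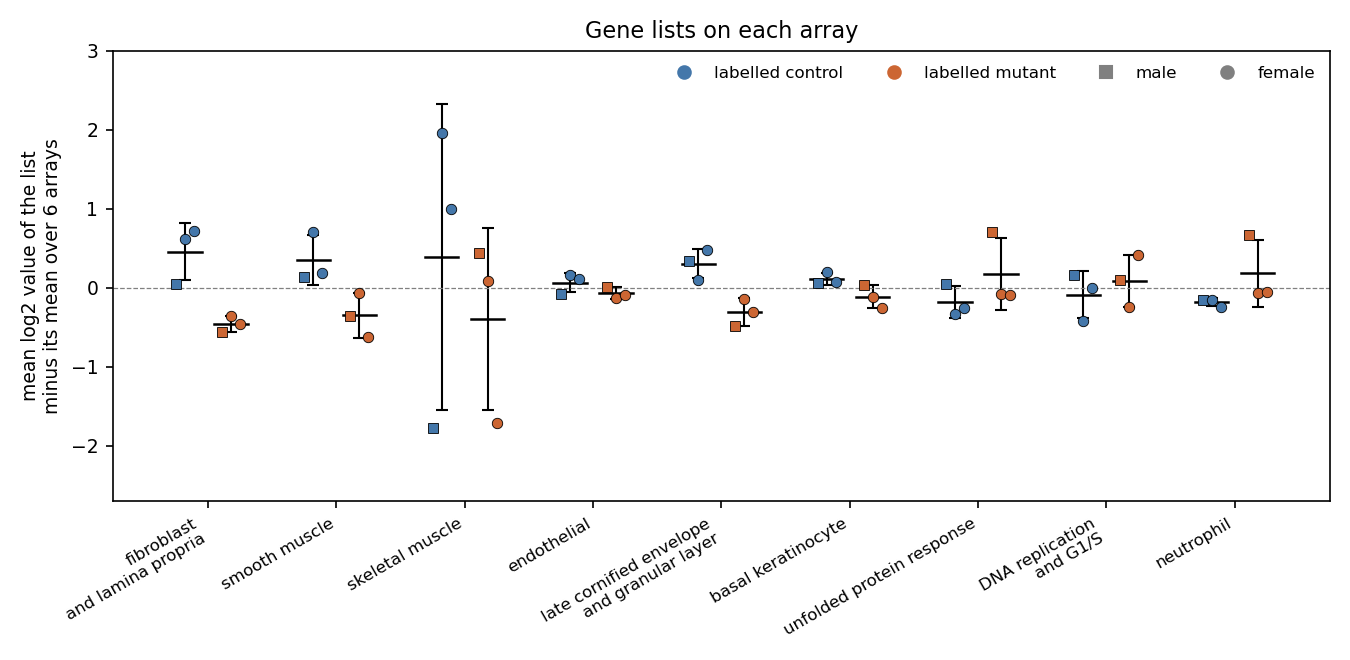
Mean log2 value of each of 9 gene lists on each array minus the list's mean over the 6 arrays (vertical axis); squares are males, circles females, blue arrays labelled control and orange arrays labelled mutant, with black bars for the mean and SD of 3 arrays. The fibroblast list lies between 0.048 and 0.71 on arrays labelled control and between -0.56 and -0.36 on those labelled mutant, and skeletal muscle spans -1.77 to 1.96 within the arrays labelled control.

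The last comparison asked whether the difference between genotypes was itself different in males and females, with 1 male per genotype. Most genes that passed were high on mutant 1 and near the control level on mutants 2 and 3. *S100a8* and *S100a9*, which encode the subunits of calprotectin, read 10.01 and 9.95 on mutant 1, the male, against 6.08 and 5.80 for *S100a8* and 5.61 and 5.32 for *S100a9* on mutants 2 and 3. *S100a8* read 4.70, 4.85 and 4.79 on controls 1, 2 and 3, so mutants 2 and 3 also lay above the controls for this gene. *Krt16*, a keratin of stressed epithelium, read 8.75 on mutant 1 and 4.44 and 4.33 on mutants 2 and 3. *Krt6b* was a further exception: it read 12.7, 11.6 and 11.7 on mutants 1, 2 and 3, above all 3 controls. It was low on the male control as well, at 6.53 against 9.88 and 9.85 on the female controls. In limma's test of the interaction, 9 genes passed: *Krt6b*, *S100a8*, *Srgn*, *Krt16*, *S100a9*, *Serpina3n*, *Lcn2*, *Ppbp* and *Bbox1*, with adjusted p-values from 0.0226 to 0.0428. The fit had 1 male per genotype, so the spread came from the females alone, and a sex difference is not separable from a difference of this 1 pair of animals.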

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

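The tests in this part were chosen after the results were seen, with these exceptions. The difference of *Klf4*, the separate test of all probe sets and the interaction with sex were planned. So were the splits of the arrays for the gene count and the spread of each array. All directions rest on the labels.

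The interaction of genotype with sex passed the test for 9 genes. It rests on 1 male per genotype, with the spread taken from the females, so its p-values decide nothing about the sexes. The values, the male difference minus the female difference on the log2 scale, were 4.61 for *Krt16*, 4.37 for *Krt6b*, 4.19 for *S100a8*, 3.64 for *S100a9*, 3.34 for *Srgn*, 3.29 for *Serpina3n*, 3.06 for *Lcn2*, 2.96 for *Ppbp* and 2.87 for *Bbox1*. On control 1, *Krt16*, *Serpina3n*, *Lcn2*, *Ppbp* and *Bbox1* read 3.86, 3.97, 3.64, 2.80 and 3.45, all under the dim limit. The sizes given for these genes, and so their places in the order, are uncertain. Outside the comparison, 7 probe sets that name no gene or several passed the limma threshold.

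The genes with an interaction were highest on mutant 1, and *Krt6b* was in addition low on control 1. Array-wide noise on mutant 1 is argued against by its spread around the group mean, 0.206 over all genes, where another array reached 0.25. Neutrophils in this animal may be a source: neutrophil markers other than *S100a8* and *S100a9* had a median 0.17 above mutants 2 and 3, with 7 of 12 higher, but 10 of the 12 lay below the dim limit and decide little. The sex of the animal cannot be told apart from this 1 animal, since there was 1 male per genotype. Epithelial stress in that animal was not tested.

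*Klf4* was higher, not lower, on the arrays labelled mutant, by 0.37 on the log2 scale. Less stroma on those arrays would raise epithelial genes alike. The 34 basal keratinocyte and desmosome genes that were neither dim nor very bright showed no such common rise. Their median was -0.085, with 21 of 34 lower, and the 14 desmosome genes alone had 0.043. The SD of 0.45 over the 34 is the spread of single genes, not the error of the median. Basal genes such as *Cd34* (-1.26) may also come from stroma and lower the median, so less stroma is not excluded. A single wrong label, or an exchange of 1 array from each group, is argued against because the 15 regroupings of that kind called 0 genes at most, against 207 for the labels. An exchange of all labels cannot be told apart from a true increase by the difference of 0.37, which did not pass, and probes outside the removed part of the gene remain possible and untested. A biological explanation, a retained or increased transcript after deletion, stays open for the same reason.

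Fibroblast, smooth muscle and skeletal muscle genes were lower on the arrays labelled mutant, with medians of -0.89, -0.78 and -0.82 above the dim limit, which may reflect how much tissue under the epithelium each preparation carried. On members as bright as the fibroblast genes, 7 endothelial genes had a median of 0.029 (SD 0.77). The 12 such macrophage and dendritic genes had -0.042 (SD 0.66), though *Flt1* and *Lyz2* among them fell. This argues against an equally lower share of endothelial and macrophage cells, weakly given the spread. Other stromal cells stay open, since the nerve and glia list held 2 such genes (median -0.41) and the lymphocyte and mast cell lists held 0. A lower share of fibroblasts and muscle would raise epithelial genes alike, and the smallest rise among the 73 genes that rose was 0.52. The same 34 basal keratinocyte and desmosome genes had a median of -0.085 (SD 0.45), and the 14 desmosome genes alone had 0.043. This argues against a common rise of that size, though basal genes such as *Cd34* (-1.26) may also come from stroma and lower the median. For the 134 genes that fell, a lower share of fibroblasts and muscle stays open as the cause, apart from the *Lce1* genes of the cornified envelope. It would raise such epithelial genes, while all 13 measured *Lce1* genes were lower (-1.89 to -0.73), 10 past the threshold. This argues against it for the *Lce1* genes. Of the 134, 14 had an upper 95% limit below the lowest fibroblast gene (-1.52). The 169 of the 207 that still passed with the score as a covariate decide little, because that covariate left the fibroblast median at -0.64. A change in fibroblasts and smooth muscle, in the preparation or in the animals, stays open.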

How the results depend on the processing

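The covariate, the females alone and the splits for the lists were chosen after seeing the data. *Klf4* stayed higher on the arrays labelled mutant and not past the threshold under all 17 alternatives (0.25 to 0.51). The gene count of 207 stayed between 164 and 270 under quantile normalization, median centring, the dim filter, other probe set rules, sex as a covariate, the intensity trend, the 1.5-fold minimum and the stroma covariate. It was 7 without moderation, 370 with array weights, 83 in the females alone and 44 to 193 with 1 array left out, where fewer arrays are fitted. With the replicate number as a block it was 81, of which 68 were among the 207; the numbers show no pairing (correlations of deviations -0.17, 0.090 and -0.10), and not every array correlated best with its own number. *Sprr2g* was the 1 gene among the 24 most changed that passed under all alternatives. Called lists numbered 0 with an estimated correlation and 0 by fry, and 11 to 18 otherwise. The interaction count stayed between 7 and 10. The 10 splits of the arrays into 3 and 3 include the labelled one and are too few for a share under 0.05. Only the labelled split gave 207 genes (highest other 0). The count of 13 lists was reached by 2 splits, the labelled one and 1 other. Differences that changed sign, none past the threshold as single genes, were *Krt4* (0.012 after quantile normalization, 0.027 in females), *Lor* (0.030 and 0.014), *Ccnd1* (0.0064 with median centring, -0.19 to 0.23 with 1 array left out), *Krt13* (-0.0018 with array weights, -0.046 with the covariate) and *Ptprc* (-0.089 in females). With 1 array left out, *Krt13* ranged from -0.037 to 0.071, *Krt14* from -0.036 to 0.27, *Mki67* from -0.013 to 0.52 and *Trp63* from -0.18 to 0.0079. With the covariate the medians of the DNA replication and skeletal muscle lists turned to -0.13 and 0.76, which for skeletal muscle follows from the score holding its genes. The cause was not tested for the others. Dim signal limits *Ivl*, most neutrophil markers, the sizes given for *Sprr2g* and *Car2*, and several genes with an interaction. Very bright signal limits *Krt4*, *Krt13* and *Lor*.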

Other observations

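The tests in this part were chosen after the results were seen, and the genes were named after their values were seen.

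Several genes outside the lists also changed between the arrays labelled mutant and those labelled control. *Plin2*, encoding a lipid droplet coat protein, rose by 1.40 ± 0.12, and *Hilpda*, an inhibitor of lipolysis on droplets, by 1.72 ± 0.27 (log2, SE; limma adjusted p = 0.00595 and 0.037), while *Pnpla3*, a lipid droplet protein, fell by 2.02 ± 0.22. The glycerolipid synthesis gene *Gpat4* rose by 0.80 ± 0.13. Amino acid transporter genes *Slc6a20a* and *Slc7a8* rose by 2.12 ± 0.28 and 1.77 ± 0.29, and the cytochrome gene *Cyp2b10* by 2.47 ± 0.35. The surface protein genes *Msln* and *Psca* rose by 1.69 ± 0.089 and 1.58 ± 0.13, and the chemokine-scavenging receptor gene *Ackr2* by 2.12 ± 0.25. These genes were not tested for enrichment.

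Changed genes of one direction lay beside each other in the order of tested genes. There were 18 such neighbouring pairs among the 207 genes, against a median of 1 in 10000 random placements (one-sided permutation p = 1e-04, the smallest they can give). Without the *Sprr* and *Lce* families, whose members may share signal, 5 pairs remained (one-sided permutation p = 0.0029): *Il1f6* with *Il1f5*, *Atp13a5* with *Atp13a4*, *Serpina9* with *Serpina12*, *Rdh13* with *Eps8l1*, and *Thy1* with *Usp2*. The first 3 of these 5 pairs are again related genes, so shared probe sequence or shared ancestry could account for most of this. The p of 0.0029 therefore does not cover unrelated neighbours. Only *Rdh13* with *Eps8l1* and *Thy1* with *Usp2* are unrelated by symbol, and they were not tested alone against the random median of 1. Regulation by neighbourhood is not shown by these data.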
